A study of Homo sapiens with 6 samples.

How the data were processed

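RNA from 6 samples of HepG2, a human liver cancer cell line, was sequenced after infection with lentivirus carrying an shRNA. In 3 libraries the shRNA was a control, and in 3 it was directed against circPRKAA1, a circular RNA made from the PRKAA1 gene. Libraries were made with a SMARTER mRNA-Seq kit, per the labels' protocols. The aligner, the counting program and the strand setting of the counting are not given in the sources used here. The submitters' processing notes list the builds GRCm38, mm10 and hg18 without a role, and the first 2 are mouse builds.

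The authors deposited whole-number counts per Ensembl gene for the 6 libraries, an exonic length per gene, and FPKM (counts scaled by exonic length and by the library's total), per the file headers. The table has 60612 genes. Of their identifiers 96.3% were found in GENCODE release 29 (GRCh38), and 99.98% of those overlapped the coordinates given there, so coordinates are given as GRCh38. The FPKM the authors deposited equalled count divided by exonic length and by the library's total within 0.0051 for 100% of genes in the 5 numbered columns. A further column of FPKM (1) carries no replicate number and was not used, and FPKM of all libraries was computed from counts, exonic lengths and totals. No identifier or symbol in the table names a circular RNA (0 rows), so the circle itself has no value here.

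Groups and replicate numbers were taken from the sample titles. The shRNA label of the knockdown samples reads as circPRKAA1, circPRKAA2 and circPRKAA3, which differs from the titles, and the titles were used. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 3.82 to 16.1).

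The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That design named limma on log2(FPKM + 1) first and edgeR if the file held raw counts. Since it holds counts, edgeR 4.0.16 (R 4.3.3) gave the main result, and limma 3.58.1 on FPKM became an alternative. Genes were kept by filterByExpr (minimum count 10, minimum total count 15) and scaled by TMM, and the quasi-likelihood test compared knockdown with control in all 6 libraries. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Levels are TMM-scaled CPM (counts scaled to a common library total). Depth was 16284262 to 20282496 counts per library. All fold changes are knockdown over control on the log2 scale.

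Tested on simulated data of this comparison with 14688 genes and 200 changed ones, edgeR recovered 73% of genes changed 1.5-fold and 92% of those changed 2-fold, with 9 false calls. When a GC trend was added to the simulation (14691 genes), edgeR made 6498 false calls without a correction and 13 with offsets for GC content and length. That trend was a smooth function of GC content, the same in all knockdown libraries, without a length trend. The offsets are fitted to such a form, so their success there was built in. It does not show how well they work in these data, where the trend varied within a group. The changed genes were drawn only from those above a minimum expected count.

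Gene lists were tested with camera (limma) on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the 44 of 46 lists that have at least 5 tested members. Camera asks whether a list differs from the other genes. With a correlation estimated from these libraries 0 lists passed, and by fry, which asks whether the members move one way on balance, 38 passed. Each list median was also set against 10000 random lists matched on GC content, exonic length and expression. Gene types, and the GC content of the longest transcript, came from GENCODE 29. Terms of the gene ontology came from the annotation in the deposited table.

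The genes named are 6 axis genes, up to 4 members with the smallest p in each list, and ACLY, ACACA, FASN and SCD. The 10 largest rises and 10 largest falls in log2(FPKM + 1), among genes that passed with groups that do not overlap, are named too. The 6 axis genes are XRCC5, XRCC6 and SREBF1, whose proteins the series title names, and PRKAA1, PRKAA2 and SREBF2, which the design added. Some genes that the rule picks are not reported here. Chance separates 3 libraries from 3 in 10% of unchanged genes.

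Alternatives were other filters, scalings (library totals, TPM, median of ratios, quantile), DESeq2 1.42.0, limma settings, protein-coding genes only, the replicate number as a block, and each library left out. Some alternatives were added after the data were seen. These were offsets per library from a smooth fit on GC content and exonic length (mgcv 1.9.3), thinned libraries, and library totals. A mean FPKM of at least 1, and mitochondrial genes left out, were also added then. Genes with near-identical copies (ribosomal protein, metallothionein and GSTA genes, FTH1, ENO1, IFITM1 and IFITM2) are uncertain, since the counting is not described. The same holds for genes that overlap another tested gene, which are SREBF1, SREBF2, ELOVL2, FADS2, CP, FILIP1L, DDC, DKK1, FOSB, HP, HNF4A, TCF7, SP5, NKD1, TAGLN, FDPS, STARD4, ACAA1, MTHFD1, SHMT2, TPI1, FTH1, BOP1, ESAM, S100A4 and WT1 among others.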

Results

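Gene-level counts were measured in 6 HepG2 libraries, 3 with a control shRNA and 3 with an shRNA against circPRKAA1. The control libraries held 16284262, 20282496 and 19126452 counts and the knockdown libraries 17047886, 17549690 and 16348435. A count was seen for 21736 ± 604 genes in control libraries and for 23978 ± 202 in knockdown libraries (SD, n = 3 each). Correlations of log2 CPM were 0.988 to 0.992 among control libraries, 0.993 among knockdown libraries, and 0.931 to 0.951 between the groups. The mean GC content of the counted genes was 50.3 ± 0.414% in control and 48.9 ± 0.124% in knockdown libraries, and mitochondrial genes took 9.56 ± 0.205% and 10.7 ± 0.584% of counts (SD, n = 3 each).

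The series title names an axis of Ku80, Ku70 and SREBP1 that drives the making of fatty acids, and the comparison asks how gene expression differs when circPRKAA1 is knocked down. The circle was not measured, so its knockdown was not checked here, and counts of the host gene PRKAA1, which were higher and not lower in the libraries labelled as knockdown, do not check it. PRKAA1 encodes the alpha-1 catalytic subunit of AMPK, the kinase that senses low cellular energy (ENSG00000132356, GRCh38 chromosome 5, 40759379 to 40798374). It stood at 31.8, 48.9 and 45.4 CPM in the control libraries and at 82.5, 76.2 and 80.7 CPM in the knockdown libraries. This rise of 0.92 on the log2 scale (SE 0.12, edgeR adjusted p = 4.28e-06) was 0.18 (SE 0.06, edgeR adjusted p = 0.0114, the highest of 26 alternatives) with offsets for GC content and length. PRKAA2, the alpha-2 subunit, rose from 18.1 ± 4.36 to 46.5 ± 3.30 CPM (SD, n = 3), by 1.36 on the log2 scale (edgeR adjusted p = 2.31e-07), and by 0.54 with the offsets.

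SREBF1, which encodes SREBP1, the transcription factor that drives lipogenic genes, fell from 124 ± 10.7 to 57.4 ± 1.39 CPM (SD, n = 3). Its log2 fold change was -1.11 (SE 0.08, edgeR adjusted p = 7.41e-09) and -1.02 with the offsets. The gene lies on chromosome 17 at 17810399 to 17837011 and overlaps RAI1 on the other strand by 1055 bases. XRCC6, which encodes Ku70 (chromosome 22, 41621163 to 41664048), fell from 686 ± 34.7 to 413 ± 26.7 CPM, a log2 change of -0.73 (SE 0.07, edgeR adjusted p = 2.47e-07), or -0.28 with quantile normalization. XRCC5, which encodes Ku80 (chromosome 2, 216107464 to 216206303), did not pass, at 475 ± 36.6 and 425 ± 9.07 CPM (log2 change -0.16, SE 0.07, edgeR adjusted p = 0.0578). SREBF2, the paralog that drives cholesterol genes (chromosome 22, 41833079 to 41907307), did not pass either, with a log2 change of -0.14 (SE 0.07, edgeR adjusted p = 0.0909). The sign of XRCC5 and SREBF2 turned with the scaling: with library totals their log2 changes were 0.04 and 0.06, and XRCC5 passed as lower with the offsets (-0.41, edgeR adjusted p = 1.96e-07, within a range up to 0.659 over the alternatives). With quantile normalization both passed as higher (0.23 and 0.19). Of the 6 axis genes 2 (PRKAA1 and PRKAA2) were higher and 2 (XRCC6 and SREBF1) lower over all genes. Adjusted over the list alone 2 were higher and 3 lower, since XRCC5 passed as well. Both higher genes are not among those of Ku80, Ku70 and SREBP1, which the title names. As a list they did not pass camera (adjusted p = 0.567), with a median of -0.15 and a mean of 0.02.

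**Figure D1:**
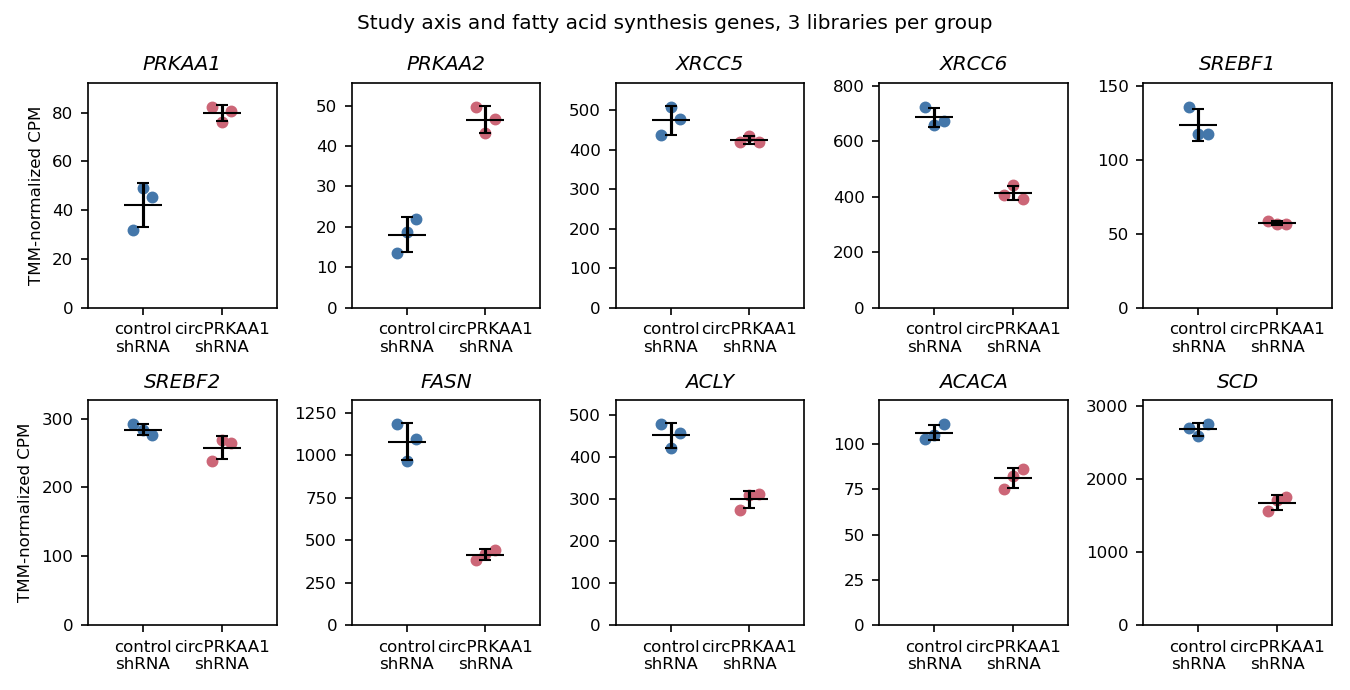
TMM-scaled CPM of the 6 axis genes and of 4 fatty acid synthesis genes in each library (points), with the group mean and SD (bars, n = 3), on linear axes from 0. SREBF1 fell from a mean of 124 to 57.4 CPM and FASN from 1081 to 415 CPM, while PRKAA1 rose from 42.1 to 79.8 CPM.

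Camera called the list of fatty acid synthesis genes lower in the knockdown libraries, though not with an estimated correlation. FASN, the fatty acid synthase (ENSG00000169710, chromosome 17, 82078338 to 82098294), fell from 1081 ± 110 to 415 ± 31.6 CPM (SD, n = 3; log2 change -1.38, SE 0.09, edgeR adjusted p = 1.29e-09). SCD, the stearoyl-CoA desaturase, fell by 0.68 on the log2 scale, and did not pass with quantile normalization (-0.04). ACLY, which makes cytosolic acetyl-CoA, fell by 0.60, and was at -0.30 with TPM scaling and -0.21 with quantile normalization. ACACA, the acetyl-CoA carboxylase, fell by 0.39, and its change did not pass in 6 of 26 alternatives, with -0.09 under TPM scaling. ELOVL2 and FADS2, which elongate and desaturate long fatty acids, fell by 1.08 and 0.84, with FADS2 overlapping FADS1 and FEN1. Of the 22 tested members of the list 14 fell, 4 rose and 4 did not pass. The counts were 14 and 4 adjusted over the list alone. SREBF1 itself is among the 14, so the list is not independent of its fall given above. The 4 that rose were ELOVL6 (0.99), ELOVL7 (1.33), ELOVL5 (0.57) and ACSS2 (0.21), named after their values were seen. With the offsets ELOVL6, ELOVL7 and ELOVL5 were at 0.54, 0.71 and 0.25, and ACACA at -0.64. The list median was -0.42 and camera called it lower (adjusted p = 0.00771, and 0.277 with an estimated correlation). With TPM scaling, library totals and quantile normalization the median was -0.13, -0.22 and -0.23. The next values are set against the median of -0.42. Matched random lists had medians from -0.48 to 0.11 (95% range), which includes that of this list.

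Over the whole transcriptome 14990 genes were tested and 10257 (68.4%) passed in edgeR, 5405 of them higher and 4852 lower in the knockdown libraries. Of these, 2107 were higher and 1197 lower by 2-fold or more. The split depends on the scaling: 52.7% of the calls were higher with TMM, 65.8% with library totals, 71.6% with TPM scaling, 60.4% with limma on log2(FPKM + 1) and 41.9% with GC and length offsets. Library totals moved the median log2 change by 0.20 and TPM scaling by 0.29, so the changes given here are relative to TMM. Of the called genes that the naming rule picks, the log2 change was more than 1.5 times smaller for 52 of 173 with quantile normalization, 35 of 180 with TPM scaling, 26 of 180 with GC and length offsets and 12 of 180 with library totals. Fold changes also followed base composition: genes of up to 40% GC had a median log2 change of 0.57, and genes above 60% GC one of -0.34. Genes with over 8000 bases of exon had a median of 0.34, and those of up to 1000 bases one of -0.33. With offsets for both properties 10428 genes passed, and 8326 (81.2%) of the calls remained in the same direction, while 262 passed with the opposite sign. Of the genes changed 2-fold or more, 1417 of the 2107 higher and 861 of the 1197 lower kept that size.

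**Figure D2:**
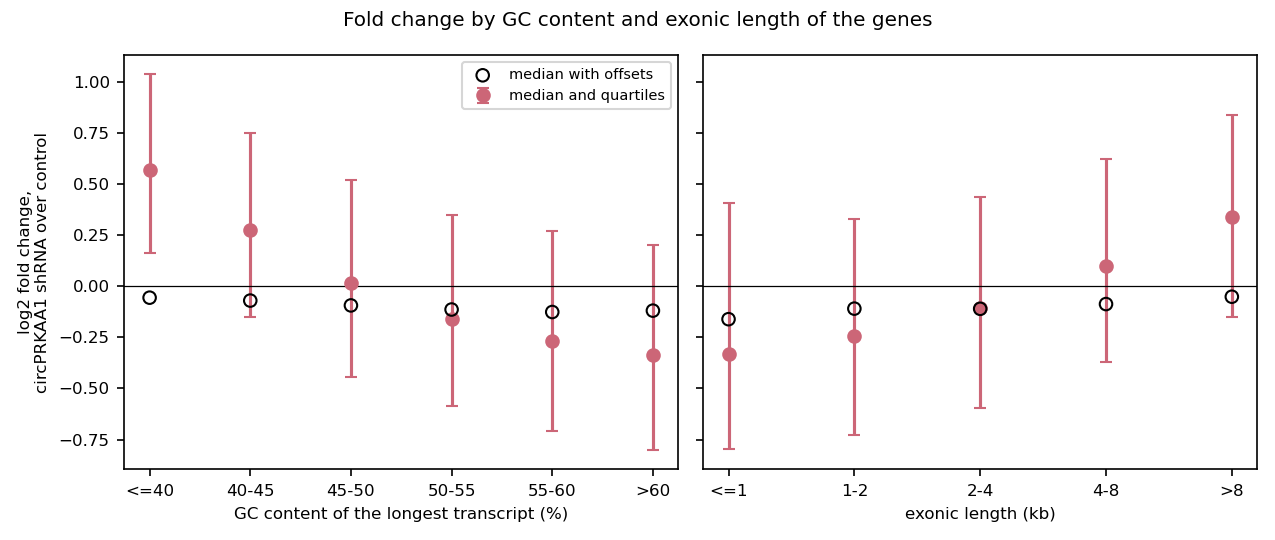
Log2 fold change (knockdown over control) by GC content of the longest transcript in percent, and by exonic length in kb, as median and quartiles of the genes in each bin (filled), and as median with GC and length offsets (open). The medians run from 0.57 at up to 40% GC to -0.34 above 60% GC, and from -0.33 to 0.34 with length. With the offsets all bins lie between -0.16 and -0.05.

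Ranked by the difference in log2(FPKM + 1), as the naming rule asks, the largest rises included FOS, an immediate early transcription factor (1.49 ± 0.17 to 61.4 ± 2.00 CPM, SD, n = 3; log2 change 5.35), and AGTR1, the angiotensin II receptor (2.22 ± 0.65 to 40.6 ± 1.28 CPM; 4.16). The nuclear long noncoding RNAs NEAT1 and MALAT1 rose by 3.36 and 3.14 on the log2 scale. CP (ceruloplasmin, which overlaps HPS3) rose by 2.87, FILIP1L (which overlaps CMSS1) by 2.90, and SAT1 (polyamine acetylation) by 2.55. CCN1 and ANKRD1 rose by 2.74 and 2.58. The largest falls on that scale included GPHA2 (-3.12), the long noncoding RNA AC011747.1 (-3.39), the metallothioneins MT1A (-2.68) and MT1G (-2.66), DDIT4 (-2.40) and UNC93A (-2.34). The values given are edgeR log2 changes, which rank genes otherwise: ROBO4 (5.09) and FOSB (4.47) lay above AGTR1, and GSTA2 (-2.73) below MT1A. SOAT2 (cholesterol esterification), DDC (which overlaps FIGNL1), the replication helicase subunit MCM2 and the WNT antagonist DKK1 fell by 2.29, 2.29, 2.23 and 2.17. In the 20 genes that the naming rule picks by size of change, not all of them named here, the groups did not overlap, which the rule asked for and chance gives in 10% of unchanged genes, and edgeR adjusted p-values ranged up to 7.07e-07 (MT1A).

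Other gene lists were fixed before the data were examined, and camera called 22 of 44, 17 as lower and 5 as higher. With an estimated correlation 0 of the 44 passed camera (9 at an unadjusted p under 0.05) and fry called 38, and with GC and length offsets 21 kept their call and direction. Of the 22, 16 had a median outside the 95% range of their matched random lists and 6 inside it. The medians of 14 of 21 called lists were more than 1.5 times smaller with quantile normalization, as were those of 15 of 22 with TPM scaling and 9 of 22 with library totals. At a mean FPKM of at least 5 the calls of fatty acid synthesis (adjusted p = 0.0929), fatty acid oxidation (0.101), glycolysis (0.0724), and the pentose phosphate, urea cycle and bile acid lists (0.0839 each) were lost. With quantile normalization those of fatty acid synthesis, fatty acid oxidation and glycolysis (0.165 each) and of the pentose phosphate list (0.102) were lost, and with TPM scaling those of YAP targets (0.0572) and matrix genes (0.0595). Over the camera alternatives the highest adjusted p of each of these lists was that with an estimated correlation, and the lowest lay between 7.65e-06 (urea cycle) and 0.00370 (matrix genes). Counts adjusted over the list alone were the same as over all genes for every list, except the axis and the hepatocyte, epithelial, coagulation and bile acid lists, whose counts are given.

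Camera called the lists of the cell cycle and of the ribosome as lower. Of 31 genes of the G1/S phase and DNA replication 29 fell and 2 rose (median -1.12, camera adjusted p = 1.95e-11; adjusted p = 0.0999 with an estimated correlation). Adjusted over the list alone the counts were also 29 and 2. Beside MCM2, UHRF1 (-2.13), MCM5 (-2.07) and CDT1 (-1.82) were among them. Of 32 genes of G2/M and mitosis 20 fell and 4 rose, with PLK1 at -1.59 and CDC20 at -1.61 (median -0.58, camera adjusted p = 0.000421; adjusted p = 0.191 with an estimated correlation). All 50 ribosomal protein genes fell (median -0.78, camera adjusted p = 3.79e-17; adjusted p = 0.318 with an estimated correlation), among them RPSA (-1.62) and RPS2 (-1.61). The median was -0.27 with quantile normalization. Their matched random lists had medians from -0.46 to -0.10. Of 23 ribosome biogenesis genes 21 fell and 0 rose, including MYBBP1A (-1.95), BOP1 (-1.82) and the nucleolar methyltransferase FBL (-1.37) (median -0.96, camera adjusted p = 1.61e-09; adjusted p = 0.0999 with an estimated correlation).

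Camera also called as lower the lists of the amino acid response, NRF2 targets, the pentose phosphate pathway, nuclear oxidative phosphorylation, the tricarboxylic acid cycle and fatty acid oxidation. In the amino acid response driven by ATF4, 21 of 29 fell and 5 rose, with the serine synthesis genes PHGDH and PSPH at -1.16 and -1.23 and SHMT2 at -1.39 (median -0.58, camera adjusted p = 0.000421; adjusted p = 0.316 with an estimated correlation). Of 22 NRF2 targets 17 fell and 3 rose (median -0.74, camera adjusted p = 0.000379; adjusted p = 0.223 with an estimated correlation). NQO1 fell by 1.18, AKR1B10 by 1.83 and ferritin heavy chain FTH1 by 1.08, while the transporter ABCC3 rose by 1.67. Of 14 genes of the pentose phosphate pathway and NADPH supply 10 fell and 1 rose, including TKT (-1.48), MTHFD1 (-1.13) and IDH2 (-1.09) (median -0.62, camera adjusted p = 0.00471; adjusted p = 0.211 with an estimated correlation). Of 37 nuclear genes of oxidative phosphorylation 24 fell and 4 rose, with NDUFB10 at -1.17 (median -0.34, camera adjusted p = 0.000460; adjusted p = 0.502 with an estimated correlation). Its call was also lost at a mean FPKM of at least 5 (adjusted p = 0.181) and with quantile normalization (median -0.01, adjusted p = 0.933, the highest of 27 camera alternatives). Of 25 tricarboxylic acid cycle genes 14 fell and 5 rose, with MDH2 at -0.98 (median -0.30, camera adjusted p = 0.0449; adjusted p = 0.316 with an estimated correlation). Of 27 fatty acid oxidation genes 16 fell and 5 rose, with ACAA1 at -1.37 and ETFB at -1.10 (median -0.34, camera adjusted p = 0.00471; adjusted p = 0.281 with an estimated correlation).

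Among 23 glycolysis genes 13 fell and 5 rose (median -0.46, camera adjusted p = 0.0277; adjusted p = 0.598 with an estimated correlation). ENO1, TPI1 and PKM fell by 1.31, 1.17 and 0.99, while HK1 rose from 2.12 to 10.9 CPM (2.37). With quantile normalization these were at -0.66, -0.53, -0.55 and 0.79. This list no longer passed with GC and length offsets (camera adjusted p = 0.170, with a range of 0.000536 to 0.598 over 27 camera alternatives). Of 23 cholesterol synthesis genes 13 fell and 4 rose, with FDPS at -0.81 against STARD4 at 1.34, or 0.58 with the offsets (median -0.31, camera adjusted p = 0.0342; adjusted p = 0.281 with an estimated correlation). Of 31 proteasome genes 18 fell and 3 rose, with PSMC3 at -0.72 (median -0.25, camera adjusted p = 0.00901; adjusted p = 0.460 with an estimated correlation). The proteasome median was 0.04 with TPM scaling, and those of cholesterol synthesis, the tricarboxylic acid cycle, oxidative phosphorylation and fatty acid oxidation were -0.02, -0.01, -0.04 and -0.05. Of 27 camera alternatives, 12 ended the call of cholesterol synthesis, 16 that of the tricarboxylic acid cycle and 9 that of the proteasome, whose direction turned in 1 more, and without knockdown replicate 3 the tricarboxylic acid cycle list did not pass (adjusted p = 0.0534, within a range of 0.000768 to 0.776 over the camera alternatives). The lists with a median inside the range of matched lists were fatty acid synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, glycolysis, cholesterol synthesis and the proteasome.

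Liver functions went both ways. Of 18 acute phase and complement genes 15 rose and 2 fell, including CP, haptoglobin HP (1.42), C5 (1.29, or 0.80 with the offsets) and CFB (0.87) (median 0.78, camera adjusted p = 0.00194; adjusted p = 0.211 with an estimated correlation). Of 21 urea cycle and amino acid catabolism genes 15 fell and 3 rose, with MAT1A at -1.91 and ASS1 at -1.34 (median -0.67, camera adjusted p = 0.00216; adjusted p = 0.336 with an estimated correlation). Of 23 bile acid and drug metabolism genes 14 fell and 4 rose, or 16 and 5 adjusted over the list alone, with GSTA2 at -2.73 and CYP3A5 at 2.55 (median -0.59, camera adjusted p = 0.00901; adjusted p = 0.240 with an estimated correlation). The hepatocyte marker list did not pass camera (adjusted p = 0.184), with 14 of 28 lower and 7 higher, or 15 and 7 adjusted over the list alone. Within it HNF4A and CEBPA, transcription factors of hepatocyte identity, fell by 1.49 and 1.34, while HP, also a member, rose by 1.42. The list median was -0.25, and 0.05 with TPM scaling and 0.17 with quantile normalization, so these 2 falls do not stand for the list.

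The lists of immediate early genes, YAP targets and matrix genes were called higher by camera with the preset correlation. Of 18 immediate early genes 11 rose and 3 fell, with FOSB at 4.47 (it overlaps ERCC1) and CCN2 at 1.84 beside FOS and CCN1 (median 0.82, camera adjusted p = 0.00471; adjusted p = 0.223 with an estimated correlation). Of 16 YAP targets 10 rose and 3 fell, with the kinase receptor AXL at 2.12 (median 0.63, camera adjusted p = 0.0122; adjusted p = 0.281 with an estimated correlation). Of 16 mesenchymal and matrix genes 8 rose and 2 fell (median 0.71, camera adjusted p = 0.0230; adjusted p = 0.281 with an estimated correlation). CCN1 and CCN2 rose in this list, and TAGLN fell by 1.85. CCN1 and CCN2 belong to all 3 of these lists. Of 16 WNT targets 13 fell and 2 rose, with DKK1, TCF7 (-1.62), SP5 (-1.42) and NKD1 (-1.17) (median -0.67, camera adjusted p = 0.000460; adjusted p = 0.191 with an estimated correlation).

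Markers of other cell types had few tested members. Of the 13 endothelial markers 6 were tested, of which 5 rose and 0 fell (median 1.60, camera adjusted p = 0.0392; adjusted p = 0.281 with an estimated correlation). Their levels were low, with ROBO4 at 4.81 ± 0.20 CPM, TIE1 at 3.38 ± 0.21 CPM and ESAM at 26.0 ± 0.75 CPM in the knockdown libraries (SD, n = 3). The log2 changes of ROBO4 and TIE1 were 5.09 and 2.97, so their control levels were lower still. The filter can keep a gene through 1 group only, and markers low in both groups drop out. The median of the tested members is therefore no fair measure of the whole list. Only 18 camera alternatives gave this list a value. Without knockdown replicate 2 the list did not pass (adjusted p = 0.0531), nor with library totals or TPM scaling (adjusted p = 0.0721 and 0.0918, within a range of 0.00752 to 0.281 over the camera alternatives). Blood and immune markers did not pass camera (adjusted p = 0.969; 3 higher and 3 lower of 9), with CD3D at 3.06 ± 0.39 CPM in the knockdown libraries. The fibroblast list and the kidney and neural list had 3 tested members each and were not tested as lists. FBN1 rose by 2.26 in the former, and PDGFRB and S100A4 fell by 0.65 and 0.51. In the latter TUBB3, PAX8 and WT1 fell by 0.48, 0.74 and 0.37, with TUBB3 at -0.29 with the offsets. With TPM scaling PDGFRB (-0.36), TUBB3 (-0.19) and PAX8 (-0.45) did not pass (edgeR adjusted p = 0.0880, 0.0991 and 0.0550, the highest of their alternatives). The calls of S100A4 and WT1 were lost in 13 of 25 alternatives each, among them without control replicate 1 (edgeR adjusted p = 0.0860 and 0.145), S100A4 also without each other library but knockdown replicate 2, and WT1 without knockdown replicates 2 or 3. With the offsets S100A4 did not pass (-0.25). The log2 change of WT1 was -0.24 without control replicate 1 and -0.0041 with limma array weights. Over the alternatives their adjusted p-values ranged from 0.00124 to 0.320 for S100A4 and from 0.00865 to 0.955 for WT1.

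**Figure D3:**
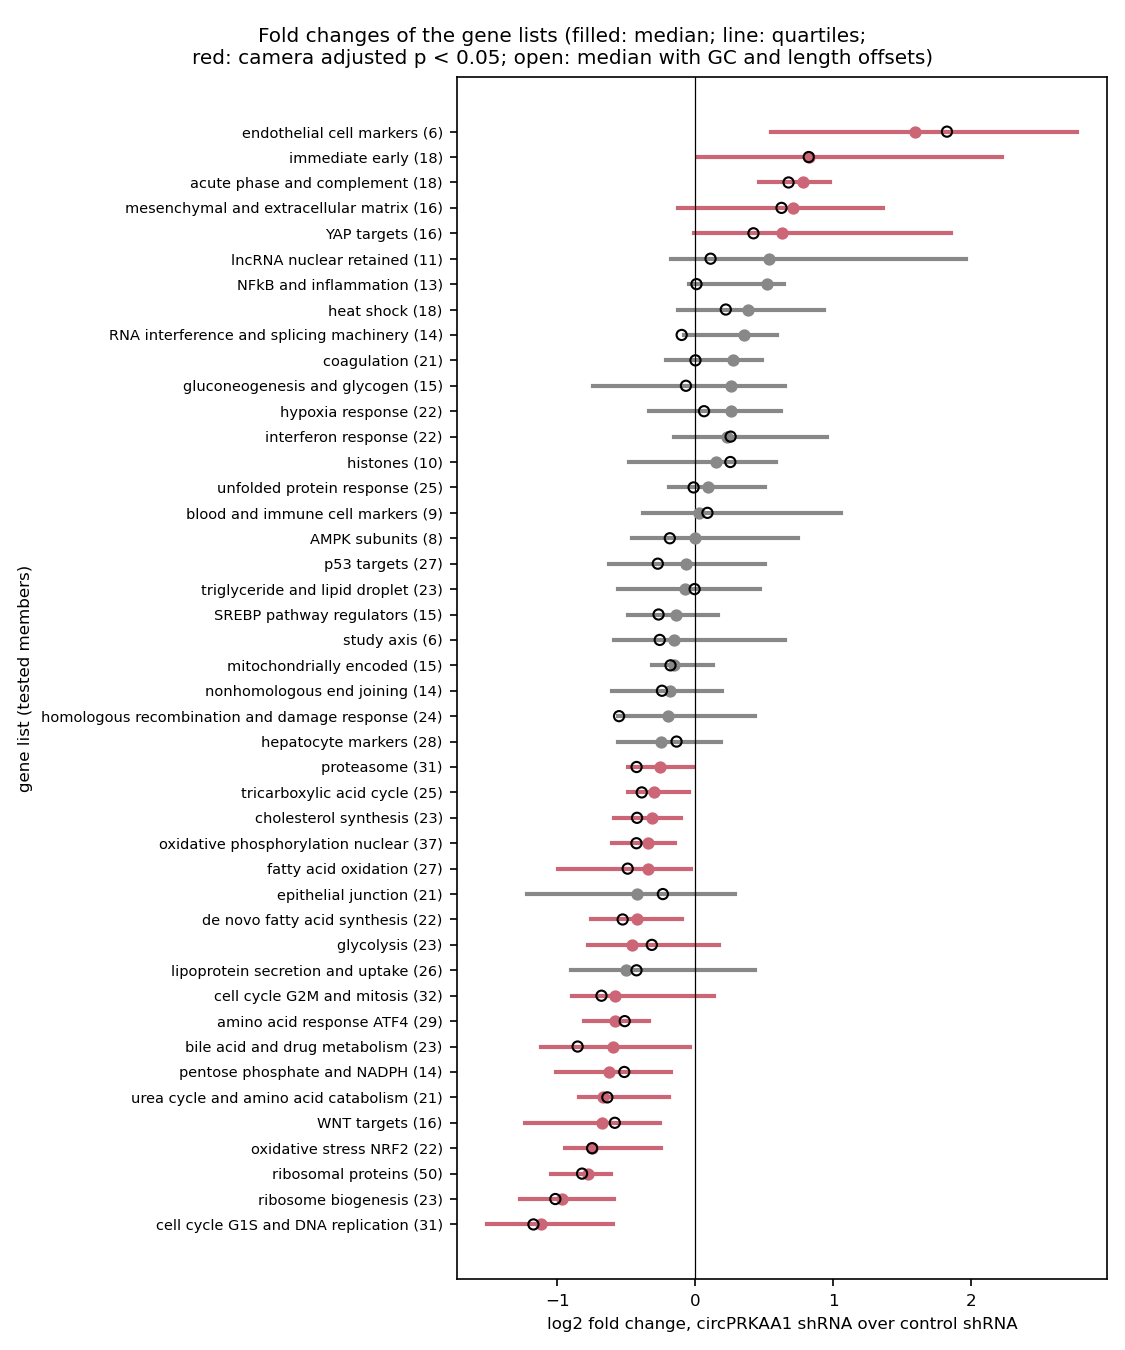
Median log2 fold change (knockdown over control, filled points) with quartiles (lines) of the tested members of each of the 44 gene lists, and the median with GC and length offsets (open points). Lists that camera called with the preset correlation are red. G1/S and replication genes lie lowest (-1.12) and endothelial markers, a list of 6, highest (1.60).

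The other lists did not pass camera. Lower medians were found for lipoprotein genes (-0.50, 14 lower and 6 higher of 26, adjusted p = 0.0661), with APOA5 at -1.91 and APOA1 at -1.10. The lipoprotein list passed in 6 of 27 camera alternatives, among them without control replicate 1 or 2 (adjusted p = 0.0471 each, within a range of 0.00295 to 0.783 over these). With no filter the hepatocyte (adjusted p = 0.00911), epithelial (0.0353) and SREBP regulator (0.0450) lists passed as lower, while their highest adjusted p over the camera alternatives was 0.851, 0.922 and 0.783. Epithelial junction genes had a median of -0.42, with 11 lower and 6 higher of 21, or 11 and 8 adjusted over the list alone (adjusted p = 0.268). SREBP pathway regulators had 7 lower and 3 higher of 15 (adjusted p = 0.291), nonhomologous end joining genes 6 and 3 of 14 (adjusted p = 0.358), with LIG4 at 1.47 (0.85 with the offsets) and XRCC6 lower, and homologous recombination genes 11 and 7 of 24 (adjusted p = 0.358). The last list passed as lower with the offsets (median -0.55, adjusted p = 0.0141, with a range of 0.0141 to 0.759 over 27 camera alternatives). Mitochondrially encoded genes had 6 lower and 3 higher of 15 (adjusted p = 0.299). The p53 targets had 11 lower and 11 higher of 27 (adjusted p = 0.586). Triglyceride and lipid droplet genes had 10 lower and 7 higher of 23 (adjusted p = 0.567, median -0.08, mean 0.02), with DGAT2 at -1.20 and LPIN2 at 1.52. AMPK subunits and kinases had 3 lower and 3 higher of 8 (adjusted p = 0.969, a mean of 0.17 and a direction that was higher by camera and lower by fry), with CAMKK2 at -0.63. Gluconeogenesis and glycogen genes had 6 lower and 7 higher of 15, with a median of 0.26 (-0.07 with the offsets), a mean of -0.02 and a camera direction of lower (adjusted p = 0.969). With TPM scaling the medians of these hepatocyte, SREBP regulator, end joining, recombination, mitochondrial, p53, triglyceride and axis lists lay above 0, from 0.05 to 0.23. With quantile normalization those of the hepatocyte, epithelial, SREBP regulator, mitochondrial, p53 and axis lists lay above 0 as well, up to 0.21.

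Higher medians were found for nuclear long noncoding RNAs (0.53, 7 higher and 3 lower of 11, adjusted p = 0.195), NFkB and inflammation genes (0.52, 7 and 3 of 13, adjusted p = 0.195), with CXCL8 at 2.04, and heat shock genes (0.38, 10 and 4 of 18, adjusted p = 0.213). RNA interference and splicing factors had 8 higher and 3 lower of 14 (adjusted p = 0.228), with AGO4 at 1.77. With the offsets the median of the nuclear long noncoding RNA list was 0.11, that of the inflammation list 0.01, of heat shock 0.22 and of the interference list -0.10. Hypoxia genes had 11 higher and 7 lower of 22 (adjusted p = 0.291), and interferon genes 12 and 5 of 22 (adjusted p = 0.299), with IFITM1 at 1.38 and OAS3 at -1.45. Genes of the unfolded protein response had 12 higher and 7 lower of 25 (adjusted p = 0.358), coagulation genes 10 and 6 of 21, or 10 and 8 adjusted over the list alone (adjusted p = 0.544), and histone genes 3 and 2 of 10 (adjusted p = 0.711). The medians of the hypoxia, unfolded protein response and coagulation lists were 0.26, 0.09 and 0.27, and 0.06, -0.01 and 0.0025 with the offsets. With quantile normalization the unfolded protein response (median 0.41, adjusted p = 0.000783), coagulation (0.39, adjusted p = 0.00402) and heat shock lists (0.59, adjusted p = 0.00151) passed as higher, and the first also at a mean FPKM of at least 5 (adjusted p = 0.0459). Their highest adjusted p over the camera alternatives was 0.608, 0.645 and 0.430.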

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

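Library totals, a mean FPKM of at least 1, GC and length offsets, thinned libraries and the omission of mitochondrial genes were chosen after the data were seen. The other alternatives were chosen before. Limma on log2(FPKM + 1) was named first in the design and became an alternative once the file was seen to hold counts. PRKAA1, PRKAA2, XRCC6 and SREBF1 kept direction and call in all alternatives that give a value (PRKAA2 has none at a mean FPKM of at least 5), with PRKAA1 from 0.18 to 1.21 and SREBF1 from -1.19 to -0.76. Leaving out each library in turn gave 4959 to 5417 genes higher and 4489 to 5159 lower; 8490 (82.8%) of the 10257 calls, and 178 of the 180 called genes that the naming rule picks, stayed in the same direction in all 6 fits, the exceptions being S100A4 and WT1.

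XRCC5 and SREBF2 did not pass in the main result and changed sign under other scalings, filters or tests. With limma on log2(FPKM + 0.1), + 0.5 and + 1 XRCC5 was at 0.041, 0.0407 and 0.0405 and SREBF2 at 0.0573, 0.0567 and 0.0559. The values for limma without trend and with robust empirical Bayes, each relative to the limma fit, were the same 0.0405 and 0.0559, and with array weights 0.0235 and 0.0858. They were 0.043 and 0.0647 at a mean FPKM of at least 5, 0.13 and 0.154 with TPM scaling, 0.0377 and 0.0599 with library totals, and 0.229 and 0.193 with quantile normalization. XRCC5 passed as lower with no filter (-0.197), median-of-ratios scaling (-0.196), DESeq2 (-0.196), the offsets (-0.414) and without control replicate 1 (-0.241). SREBF2 passed as lower with DESeq2 (-0.176) and without control replicate 2 (-0.190). Leaving out a library gave -0.241 to -0.154 for XRCC5 and -0.193 to -0.0899 for SREBF2. With quantile normalization MT-ND3 (0.177), MT-ND5 (0.0288) and LYZ (0.294) changed sign, as did SOD2 with the offsets (-0.0108), and the proteasome list was no longer called (median 0.03, adjusted p = 0.783, with a range from 2.68e-05 over its alternatives). With library totals only the scaling differs from the main fit, so there the sign of XRCC5 and SREBF2 turned with the scaling, which moved the median of all genes by 0.20. For the other settings, and for the other genes and the proteasome list, the cause was not tested.

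Some counts moved by more than 1.5 times. The limma fits differ from edgeR in filter, scaling, test and pseudocount at once, so the part of each in the difference from edgeR was not separated. The limma fits at pseudocounts of 0.1, 0.5 and 1 differ in the pseudocount alone, and their 2-fold counts fell as it grew. Genes lower by 2-fold or more numbered 540, 432 and 344 with limma at pseudocounts of 0.1, 0.5 and 1, and genes higher 1122 and 788 at the last 2. Limma without trend gave 786 higher and 343 lower by 2-fold, robust empirical Bayes 784 and 343, array weights 763 and 352, and quantile normalization 485 and 467. A mean FPKM of at least 1 left 1164 genes higher by 2-fold, and of at least 5 left 2437 higher and 2478 lower, 475 and 343 of them by 2-fold. TPM scaling gave 2956 genes lower, 3213 higher by 2-fold and 555 lower by 2-fold, and library totals 709 lower by 2-fold. The fatty acid synthesis list was no longer called at a mean FPKM of at least 5 (adjusted p = 0.0929), with quantile normalization (0.165) and with an estimated correlation (0.277), over a range of 0.000115 to 0.277; the cause was not tested. Lists called were 12 at a mean FPKM of at least 5, 0 with an estimated correlation and 38 by fry.

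With the replicate number as a block 9843 genes passed. Deviations of libraries with the same number correlated at -0.0918, -0.149 and 0.0407, so the numbers are not shown to pair the libraries, and not every library correlated best with its own number. Some smaller changes can go uncalled: of 1.5-fold changes simulated over 14688 genes at these depths (16284262 to 20282496 counts) 73% were recovered. Depth was not varied in the simulation, so the missed share cannot be laid to depth. It changed 200 genes, far fewer than the 10257 that passed in the data, so its shares may not hold there.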

Other observations

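The fits with GC and length offsets and with thinned libraries, the list test with offsets, the test on the larger adjusted p of PRKAA1 and PRKAA2, and the tests of gene ontology terms were chosen after the results were seen. Camera over 873 gene ontology terms called 44, with 37 lower and 7 higher, and 38 kept their call with GC and length offsets. With an estimated correlation 0 terms passed camera (35 at an unadjusted p under 0.05), and the adjusted p of each term named here was then 0.898. Autophagosome assembly genes were higher (18 rose and 0 fell of 23, median 0.53, adjusted p = 0.00602, adjusted p = 0.898 with an estimated correlation, and a median of 0.29 and adjusted p of 0.00318 with the offsets). Homophilic cell adhesion genes were higher (35 rose and 6 fell of 55, median 0.59, adjusted p = 0.0105, and 0.000592 with the offsets), and this term holds cadherin families with similar copies. Genes of Golgi to plasma membrane transport were higher as well (11 rose and 0 fell of 15, median 0.52, adjusted p = 0.0202, and a median of 0.24 and adjusted p of 0.0327 with the offsets). Spliceosome genes were lower (69 fell and 29 rose of 127, median -0.33, adjusted p = 0.00644, and 7.43e-05 with the offsets), as were nucleocytoplasmic transport genes (17 fell and 3 rose of 23, adjusted p = 0.0104, and 0.000178 with the offsets).

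Most tested genes differed between the groups (10257 of 14990). With GC and length offsets 10428 genes passed. That count includes new calls, and standard errors of the axis genes were smaller, so alone it cannot decide. Of the 10257 calls 8326 (81.2%) passed in the same direction with the offsets, and 262 with the opposite sign. This argues against base composition, as the offsets model it, as the source of most calls. Depth is argued against by 10149 genes passing with all libraries thinned to the smallest total. Of the 10 splits of the 6 libraries only the real one (1) gave as many genes, with 10257 against 0 at most by edgeR for the others (86 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. More unspliced or nuclear RNA in the knockdown libraries may contribute and stays open: sense intronic genes lay at percentile 81.5 of matched lists, between the bounds set before, while MALAT1 and NEAT1 rose by 3.14 and 3.36 and intergenic long noncoding RNA genes lay at percentile 0.12. An effect of the knockdown also stays open, and the labels give no preparation batch to test.

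The fatty acid synthesis list was called lower by camera, with a median of -0.42. Against matched random lists this median lay at percentile 4.72, which by the bounds set before neither excludes nor shows a part played by GC content and length. The list remained lower with the offsets (camera adjusted p = 0.00541), and of FASN and SREBF1 the smaller change was -1.02 with the offsets, which argues against base composition as the whole cause. A lower expression of SREBP1 target genes after the knockdown is a candidate explanation that was not tested here. The call of the list is lost with an estimated correlation (camera adjusted p = 0.277), with quantile normalization (0.165) and at a mean FPKM of at least 5 (0.0929). Its median was -0.13 with TPM scaling and -0.22 with library totals.

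PRKAA1 and PRKAA2, of 35.3% and 35.2% GC, were higher in the knockdown libraries. With the offsets the smaller rise was 0.18, and 19.5% of the log2 change of PRKAA1 and 39.96% of that of PRKAA2 were left. The bound set before asked for at least 50% to be left, so how much of the rise is base composition cannot be told apart from a change in expression. For base composition as the whole cause, the test chosen afterwards gave a larger edgeR adjusted p of 0.0114 with the offsets. Since 10428 of 14990 genes passed with the offsets, and the remaining rise of PRKAA1 is small, this test cannot decide that question.

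A hypothesis was that a gain or loss of whole chromosomes in one population may shift gene medians by chromosome. Without offsets chromosome medians followed GC content (rho -0.868 over 23 chromosomes). With offsets the furthest was chromosome 22 at -0.21, between the bounds set before, so the question stays open. The median over all genes was -0.09 in that fit, so part of this value is a shift common to all genes.

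The GC trend also varied within a group. The median of genes under 40% GC minus that of genes of 60% GC or more, relative to the mean of all libraries, was -0.81, -0.17 and -0.41 on the log2 scale in control libraries 1 to 3, and 0.52, 0.37 and 0.50 in knockdown libraries 1 to 3. Processed pseudogenes were lower (348 genes, median -0.47, percentile 0 of matched lists). As copies of other genes they are uncertain in the same way as the genes with near-identical copies, since the counting is not described.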
